A study of Mus musculus with 6 samples.

How the data were processed

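Lung CD45+ Epcam- cells of 6 mice, 3 Ctrl and 3 Goblet-Y/T, were sorted alive after collagenase digestion and red cell lysis, 10000 cells per sample, and made into 3' droplet libraries. The deposited matrices hold UMI counts per gene and barcode, raw whole numbers for 32285 features and 38342 barcodes. The submitters' processing notes name Cell Ranger, Seurat 5.0.1 and the mm10 build; the Cell Ranger version, the annotation and the filter behind the deposited barcodes are not given in the sources used here. Every barcode held at least 500 UMIs. No deposited cell annotation was used, so cell names were rebuilt from markers and can differ from the submitters' own. Groups and replicate numbers came from the sample titles. All 15 pairs of libraries differed beyond sampling noise (chi-square per degree of freedom of 19.4 or more), so each counted as 1 sample.

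Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored with Scrublet as held in scanpy 1.11.5, and in each library the highest scores were removed at 0.8% per 1000 barcodes, because the automatic threshold marked 0.0454% of Ctrl 3; this rule was chosen after seeing the data. The 31871 kept cells were scaled to 10000 UMIs and clustered on 2000 variable genes (sex-linked, mitochondrial and antigen receptor segment genes left out), 30 principal components, 20 neighbours and Leiden resolution 1.5, without batch correction. Of 35 clusters 28 were named X-like from markers fixed before the data were examined, giving 15 classes. A name needed at least 3 markers of the type, and clusters with more leading genes of another type, markers of another lineage, few UMIs without a leading marker, or a median doublet score over 0.12 stayed unnamed; these thresholds were set after seeing the data. The 7 unnamed clusters held 7.93 ± 2.37% of Ctrl and 6.50 ± 1.11% of Goblet-Y/T cells.

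Counts were summed per library and class, and the 11 classes with at least 20 cells in every library, and all kept cells together, were tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood fit and F test, Goblet-Y/T against Ctrl, two-sided) in R 4.3.3. The standard error of a log2 fold change is its size divided by the square root of the F statistic. A gene changed where its Benjamini-Hochberg adjusted p was under 0.05 within its class. The genes named were those past that threshold with a mean of 20 CPM or more and all 3 Goblet-Y/T libraries on one side of all 3 Ctrl libraries. They were the 12 with the largest log2 fold change each way in the 3 classes with the most changed genes and in all sorted cells, and 5 each way elsewhere, leaving out sex-linked, predicted and receptor segment genes. Where a class had none, genes of the smallest p could be named as not past it. Any member of a fixed gene list could be named beside its list. Some genes that these rules select are not reported here. There were 39 such lists, tested per class with at least 5 tested members by limma's camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives, adjusted over the lists of a class. Shares of kept cells were compared with exact permutation tests and with edgeR on cell numbers. Gene positions came from GENCODE M21 on GRCm38, in which all 472 looked-up identifiers were found.

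The alternatives chosen before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, each library left out, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), no cell filter, doublets kept, and Leiden resolutions 0.8 and 2.5. Scrublet's automatic threshold, sex as a covariate, and a wider and a narrower alveolar macrophage-like class were chosen after seeing the data. The gene test was tested on simulated data after it had been run on the deposited counts, with 200 changed genes. With the counts of the alveolar macrophage-like class it recovered 28.4% of 1.5-fold, 70.1% of 2-fold and 97.0% of 4-fold changes among 10446 genes, and called 14 unchanged genes beside the 19, 47 and 64 changed ones. With those of the CD4 class it recovered 26.9, 67.2 and 92.4% among 7472 genes and called 9 unchanged genes beside 18, 45 and 61 changed ones. In both, the share of unchanged genes among the calls was above the 0.05 that the adjustment aims at. With nothing changed, 0 of 24 and 0 of 20 simulated lists were called. With 1 list raised 2-fold it was called in both, with 1 other list in the alveolar macrophage-like class. Each gene was drawn independently, so the simulated lists held no correlation between genes. They therefore do not show how often camera with a preset correlation calls lists of correlated genes. CPM intervals for genes with few UMIs cover counting error only.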

Results

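Live CD45+ Epcam- cells, which are lung leukocytes with the epithelium excluded, were profiled by droplet single-cell RNA sequencing of 3' ends in 6 mice. The Goblet-Y/T group held 3 animals that carried Scgb1a1-CreERT, a tamoxifen-inducible Cre recombinase driven by a gene of airway secretory cells. The Ctrl group held 3 animals of the Y/T line without the driver, and the labels did not spell out the Y/T alleles. All 6 animals had received tamoxifen at 75 mg/kg on 5 consecutive days, and lungs were taken 7 days after the last dose. The deposited counts summed to 58930785, 53143300 and 46696726 UMIs in Ctrl 1, 2 and 3 and to 72427886, 44119409 and 34224825 in Goblet-Y/T 1, 2 and 3. After filtering, 6112, 6140 and 5275 Ctrl cells and 5808, 4712 and 3824 Goblet-Y/T cells remained. Total UMIs (exact permutation p = 0.9, two-sided, n = 3 per group) and median UMIs per cell (5850 ± 363 against 5778 ± 925, SD, exact p = 0.9) differed by less than the spread between animals. Each library was 1 animal and 1 replicate, errors on CPM and on shares are SDs over n = 3 libraries, and errors on log2 fold changes (Goblet-Y/T over Ctrl) are standard errors.

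The comparison asks which immune cells of the lung, and which of their genes, differ between tamoxifen-treated mice with and without the airway driver. The Ctrl animals lacked the recombinase, so an effect of the recombinase with tamoxifen is not separated from that of the recombined alleles. Recombination itself takes place in epithelium, outside the sorting gate, and could not be checked here. Scgb1a1, the secretory marker that drives the recombinase, was present at 2.24 ± 0.699 CPM in Ctrl and 1.44 ± 0.364 CPM in Goblet-Y/T (exact permutation p = 0.2, two-sided, n = 3). From Xist, the X inactivation transcript, and the Y-linked Ddx3y, Ctrl 1, Ctrl 2 and Goblet-Y/T 1 were female and Ctrl 3, Goblet-Y/T 2 and Goblet-Y/T 3 were male.

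In the alveolar macrophage-like cells the genes of cholesterol and fatty acid synthesis rose together in Goblet-Y/T. All 17 tested members of that list were higher, over all genes tested and also when adjusted over the list alone, with a median log2 fold change of 1.71. Fdps, which makes farnesyl diphosphate, rose from 71.4 to 378.1 CPM (log2 fold change 2.39 ± 0.14), and Sqle, the squalene epoxidase, from 34.9 to 161.4 CPM (2.17 ± 0.12). The sterol-responsive transcription factor gene Srebf2 rose by 1.05 and Acly by 0.66, the smallest rise of the list. Against the other genes of the class the list passed camera (adjusted p = 2.60e-53 with a preset correlation), and adjusted p = 0.0817 with an estimated correlation. Sqle is ENSMUSG00000022351, protein-coding, at chromosome 15, 59315077 to 59331192 on GRCm38.

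Among the genes that fell in the same cells were some of cholesterol efflux and lipid handling, which were not tested as a group. Abca1, a cholesterol efflux transporter (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895), went from 105.0 ± 9.11 to 6.89 ± 0.742 CPM, a log2 fold change of -3.96 ± 0.13. Abcg1, a transporter of the same kind, went from 1293 to 599 CPM (-1.11 ± 0.11). The apolipoprotein genes Apoc1 (-3.96 ± 0.22) and Apoe (-2.20 ± 0.43) fell, as did Mylip, an E3 ubiquitin ligase (-3.02 ± 0.21). Further genes that fell were Cidec, a lipid droplet protein (-1.83 ± 0.11), Fabp1, a fatty acid binding protein (-2.06 ± 0.22), Acot1, an acyl-CoA thioesterase (-2.87 ± 0.19), and Acaa1b, a peroxisomal thiolase (-3.32 ± 0.30). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 4.07e-09 for Abca1 and 0.0279 for Apoe, the highest of these.

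Genes that interleukin 4 and interleukin 13 induce in macrophages rose in the alveolar macrophage-like class. Of 15 tested members of the type 2 myeloid list 11 rose, 1 fell and 3 did not pass, and 12 rose and 1 fell when adjusted over the list alone. Arg1, the arginase (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), rose from 0.924 ± 0.302 to 328 ± 201 CPM (log2 fold change 8.72 ± 0.89). Chil3, a chitinase-like protein, rose from 12200.0 ± 1567 to 38060.0 ± 5834 CPM (1.64 ± 0.13), and the chemokine gene Ccl17 from 2.02 ± 2.19 to 179 ± 124 CPM (5.76 ± 1.16). Irf4, a transcription factor, rose by 3.08, Il4ra, which encodes a receptor subunit for both cytokines, by 1.03 ± 0.13, and Mrc1, the mannose receptor, by 0.58 ± 0.09, while Flt1 fell (-0.83). Ccl24, an eosinophil chemokine, had no UMI in the Ctrl cells and 280 ± 188 CPM in Goblet-Y/T, with an adjusted p of 0.104. The median of the list was 1.64, also with Ccl24 at its lower bound, and camera gave adjusted p = 1.06e-11, with adjusted p = 0.239 with an estimated correlation.

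Spp1, which encodes osteopontin, rose in the same class from 322 ± 108 to 3524 ± 1251 CPM (log2 fold change 3.45 ± 0.42), and Fn1, fibronectin, by 2.59 ± 0.19. Mmp12, the macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), rose from 12.6 to 532 ± 111 CPM (5.43 ± 0.49). In the lipid-associated and fibrosis-associated list 9 of 17 members rose, 2 fell and 6 did not pass, with 10 up and 2 down adjusted over the list alone (median 0.63). The members that fell, Lpl (-1.03) and Apoe, encode a lipoprotein lipase and an apolipoprotein. Its camera adjusted p was 2.43e-05, and adjusted p = 0.191 with an estimated correlation. Timp1, a metalloproteinase inhibitor, rose by 5.33 ± 0.85 and the cytokine signalling inhibitor Socs3 by 3.71 ± 0.46. Ccl17 was more abundant in the interstitial macrophage-like class, at 997.7 CPM in Goblet-Y/T.

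The markers of resident alveolar macrophages moved both ways. Of 22 tested members 6 rose, 9 fell and 7 did not pass, with 7 up and 9 down adjusted over the list alone (camera adjusted p = 0.0962, median -0.29). Ear1, an eosinophil-associated ribonuclease (ENSMUSG00000072601, chromosome 14, 43818765 to 43875517), went from 561 ± 18.1 to 40.8 ± 12.5 CPM (-3.76 ± 0.21), Ear2 fell by 1.59 and the scavenger receptor Cd36 by 1.59. Pparg, the lineage's nuclear receptor, fell from 120.4 to 96.9 CPM (-0.31). Car4, carbonic anhydrase 4, rose from 530.0 to 2645 CPM (2.32 ± 0.13) and Ctsk from 513 to 1295 CPM. Siglecf (125.2 against 70.6 CPM, adjusted p = 0.138) and Marco (adjusted p = 0.638) did not pass.

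Other fixed lists also lay higher in these cells. Oxidative phosphorylation had 14 of 26 members up and none down (17 adjusted over the list alone, median 0.37). Glycolysis and hypoxia had 9 of 15 up and 1 down (11 and 2 over the list alone), with the glucose transporter Slc2a1 at 2.09. The unfolded protein response had 8 of 13 up, the chaperone Hspa5 rising from 639 to 1256 CPM. Chemokines had 5 of 15 up (Ccl6, Ccl9, Ccl17, Cxcl14 and Cxcl16), and neutrophil granule and activation genes 4 of 11 up and 1 down. NF-kB cytokines had 5 of 22 up and 1 down, among them Il1b (111 ± 71.7 to 784 ± 181 CPM). Complement and efferocytosis had 5 of 11 up and 2 down, the efferocytosis receptor Mertk falling from 249.8 to 136.4 CPM. Ribosomal proteins had 7 of 24 up and MHC class II 1 of 9 up (H2-DMb1, 7 over the list alone). Camera adjusted p for these 9 lists ran from 2.88e-06 (chemokines) to 0.0063 (complement and NF-kB). With an estimated correlation the lowest adjusted p of the 12 lists that passed was 0.0817 (cholesterol). With fry 9 of the 12 passed. Lists that did not pass included the type I interferon response (3 of 16 up, adjusted p = 0.138), the TGF-beta response (1 of 12 up, 5 down, 0.623), the interferon gamma response (1 of 15 down, 0.861) and the cell cycle (0 of 20 changed, 0.685).

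Across the class, 2237 of 10449 tested genes changed, 1197 higher and 1040 lower, and 521 of them by more than 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p of 0.05, two-sided; DESeq2 called 1830, of which 1738 were among the 2237). The 3 values of a group lay apart from those of the other in 39.8% of tested genes, against 10% by chance. Library sums ran from 2117484 to 22704425 UMIs. Median UMIs per cell of the class were 15393, 19824 and 19501 in Ctrl and 22832, 29713 and 31107 in Goblet-Y/T, so depth per cell differed without overlap. Fbp1, a gluconeogenic enzyme, had 1 UMI in Ctrl and 1597 in Goblet-Y/T (ratio of UMI fractions 980, 95% counting interval 176 to 38730), and Rnase2a, a ribonuclease, 3 against 1717 (351, 120 to 1705). Different clusters held most of the class: cluster 9, led by Ear1 and Lpl, held 87.5% of its cells in Ctrl and 8.04% in Goblet-Y/T on average, and cluster 11, led by Spp1 and Car4, 3.02% and 85.7%. Within cluster 9 alone 52 genes changed, 42 of them among the 2237, and within cluster 11 alone 33, of which 30, with as few as 8 and 2 cells in a library. The clusters were drawn from the same expression values, so these counts do not show how much of the difference lies within a cluster. The count of the whole class fell to 1300 without Ctrl 1, 1277 without Goblet-Y/T 2 and 1407 without Goblet-Y/T 3, with no sign changes. Of the 24 genes selected by rule, 7 were no longer past the threshold without Ctrl 1 (Fbp1, Rnase2a, AA467197, Ccl17, Timp1, Gatm and Apoe). They were 4 without Ctrl 2, 5 without Ctrl 3, 5 without Goblet-Y/T 2, and 1 each without Goblet-Y/T 1 (Apoe) and Goblet-Y/T 3 (Ccl17). MHC class II was the list among the 12 whose call ended without a library (Ctrl 1). Values of genes with near-identical copies, such as Ear1, Ear2 and Rnase2a or Chil3 and Chil4, are uncertain to the extent that counting split their reads.

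The interstitial macrophage-like class held interstitial macrophages and dendritic cells, and 66 of 9580 genes changed in it. Nkg7, a protein of cytotoxic granules (ENSMUSG00000004612, chromosome 7, 43437073 to 43438249), went from 36.7 ± 1.58 to 5.32 ± 1.72 CPM (log2 fold change -2.80 ± 0.25). Granzyme B (Gzmb, -4.40) and Ctsw (-2.28) fell too, so that 3 of 8 cytotoxic members fell, 6 adjusted over the list alone. H2-Oa, which modulates peptide loading on MHC class II, fell by 2.27 on the log2 scale, Ms4a4b, a lymphocyte membrane protein, by 1.68, and Hpgd, which degrades prostaglandins, by 1.64. AA467197 rose from 74.1 to 495.2 ± 163 CPM (2.73 ± 0.29) and Vdr, the vitamin D receptor, by 1.56 ± 0.27. Adam8, a membrane protease, rose by 1.33 ± 0.20, the ornithine decarboxylase Odc1 by 1.09 and Tgfbi by 0.90 ± 0.14. The class was 1 cluster, and at a finer resolution most of it divided into an interstitial macrophage part and a part with markers of conventional type 2 dendritic cells, which held 32.5, 47.1 and 40.2% of it in Ctrl and 44.8, 33.1 and 41.9% in Goblet-Y/T.

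Of 30 lists tested in the interstitial macrophage-like class, 13 passed camera with a preset correlation and 0 with an estimated one. The cytotoxic list had a median of -2.54 (adjusted p = 1.10e-15, and adjusted p = 0.0924 with an estimated correlation). Cells with at least 2 UMIs of lymphocyte genes made up 9.82, 25 and 22.0% of the class in Ctrl and 18.3, 11.6 and 18.8% in Goblet-Y/T, and the median was -1.06 without them. It was 0.22 in the interstitial macrophage part and -2.49 in the dendritic part, so the interstitial macrophage part did not share the direction. In the type I interferon response 1 of 23 members fell, Ifit3 (13.03 ± 5.06 to 1.13 ± 0.982 CPM), and 10 adjusted over the list alone. Its median was -0.88 (adjusted p = 9.63e-13, and adjusted p = 0.424 with an estimated correlation), and -0.37 without the cells with lymphocyte UMIs. It was -0.78 in the interstitial macrophage part and -0.78 in the dendritic part. The cholesterol list had 0 of 17 members past the threshold over all genes and 8 up adjusted over the list alone. Its median was 0.59 (adjusted p = 9.63e-10, and 0.424 as the adjusted p with an estimated correlation). Type 2 myeloid genes had 1 of 18 up, Pdcd1lg2, a checkpoint ligand, at 2.08 ± 0.39, and 2 adjusted over the list alone. The list had a median of 0.82 (adjusted p = 2.57e-06, and adjusted p = 0.195 with an estimated correlation). Retnla, the resistin-like protein most abundant in this class, was at 7960.0 ± 1195 and 9764 ± 848 CPM (adjusted p = 0.252). The glycolysis list (10 up and 1 down over the list alone), oxidative phosphorylation (2 up), the unfolded protein response (6 up) and the lipid-associated list (3 up) lay higher. Naive lymphocyte, interferon gamma, MHC class II, MHC class I and type 2 lymphocyte genes lay lower. For these 9 lists camera gave an adjusted p between 3.57e-08 and 0.0108, and an adjusted p of 0.424 or more with an estimated correlation.

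By edgeR's quasi-likelihood test 28 of the 66 genes of the interstitial macrophage-like class were higher and 38 lower, and DESeq2 called 198. With sex as a covariate, an alternative added after seeing the data, 37 genes changed and 30 of the 66 stayed called. The count was 390 without Ctrl 1, 31 without Ctrl 2, 7 without Ctrl 3, 102 without Goblet-Y/T 1 and 2 without either Goblet-Y/T 2 or Goblet-Y/T 3. Of the 24 genes named by rule, 14 were lost without Ctrl 2, 20 without Ctrl 3, 5 without Goblet-Y/T 1 and 23 without Goblet-Y/T 2 or Goblet-Y/T 3, and Nkg7 stayed past the threshold in all 6 of these fits. At the finer resolution the interstitial macrophage part alone had 4 changed genes, where Ms4a4b was at 0.61, and the dendritic part 77, of which 41 were among the 66. The lists of MHC class I (adjusted p = 0.451), MHC class II (0.235), lipid-associated (0.127) and interferon gamma genes (0.240) lost their call without Ctrl 2. The first 3 lost it also without Goblet-Y/T 1 (0.0592, 0.136 and 0.140), and type 2 lymphocyte genes without Ctrl 1 (0.108) or Goblet-Y/T 2 (0.0806).

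**Figure D1:**
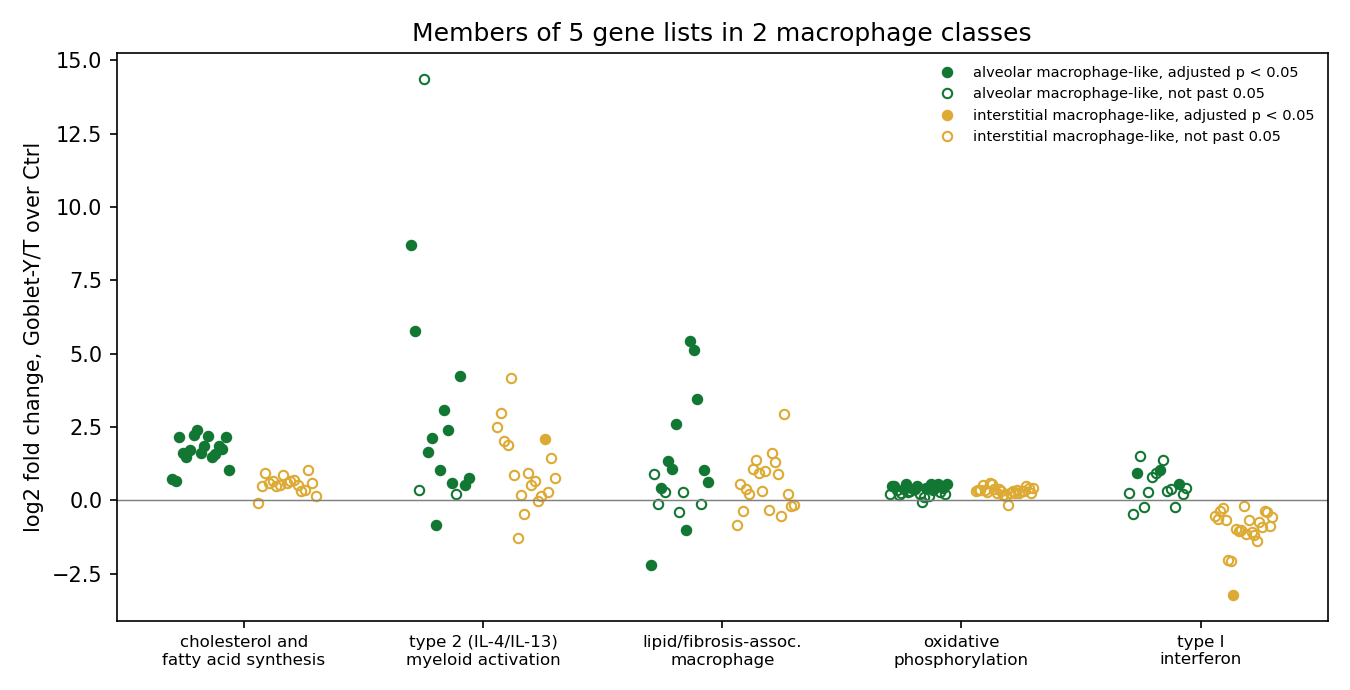
Log2 fold change (Goblet-Y/T over Ctrl) of each tested member of 5 gene lists in the alveolar and interstitial macrophage-like classes; each point is a gene, filled where its adjusted p was under 0.05, with no error bars. All 17 cholesterol genes are filled and above 0 in the alveolar class, and the highest type 2 point is Ccl24, a fitted value with no Ctrl UMI.

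In CD4 T cell-like cells 9 of 7453 genes changed (8 up, 1 down; DESeq2 called 9, of which 6 were the same). Irf1, an interferon-induced transcription factor, rose from 94.95 ± 6.70 to 180 ± 24.2 CPM (log2 fold change 0.92 ± 0.13, adjusted p = 0.000222 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in 3 of 3 libraries). The inhibitors of cytokine signalling Socs3 (1.72 ± 0.24, adjusted p = 0.0321) and Socs1 (0.75, 0.037), the NF-kB regulator Nfkbiz (0.69, 0.020) and the cell cycle inhibitor Cdkn2d (0.94, 0.037) rose, and Ttc28 fell (-1.01 ± 0.20, 0.0305). In CD8 T cell-like cells Sbno2, a transcriptional regulator (ENSMUSG00000035673, chromosome 10, 80056992 to 80105571), rose from 17.2 to 56.6 ± 16.5 CPM (1.72 ± 0.19, adjusted p = 1.76e-05). In regulatory T cell-like cells, a class that also held activated CD4 cells, it rose from 27.6 to 87.9 CPM (1.68 ± 0.25, 0.00265). The CD8 class had 2 changed genes of 8932 and the regulatory class 1 of 6576. The other gene of the CD8 class was Gadd45g, a stress response gene (1.38 ± 0.25, adjusted p = 0.0359), below the level set for naming and chosen after its values were seen. No gene passed in NK cell-like (0 of 8595; 284 at an unadjusted p of 0.05; 0 by DESeq2) or B cell-like cells (0 of 11044; 275 unadjusted; 6 by DESeq2). With the replicate number as a block 7 genes passed in NK and 2 in B cells, with no filter on low counts 9 and 42, and with sex as a covariate 0 and 14, all 14 higher. In NK cells the smallest p belonged to Klra5 (-1.20, adjusted p = 0.649), and in B cells to Retnla (1.21 against 6.18 CPM, 0.0786).

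The interferon gamma list passed camera in CD4 T cell-like cells (2 of 14 members up, 2 up and 1 down adjusted over the list alone, median 0.19, adjusted p = 0.000855, and adjusted p = 0.685 with an estimated correlation). So did NF-kB cytokines (1 of 8 up, adjusted p = 0.0158) and MHC class II (0 of 6, 0.0352), with adjusted p of 0.685 and 0.842 with an estimated correlation. Regulatory T cell genes lay higher in the regulatory class (0 of 10 past the threshold, 3 adjusted over the list alone, median 0.35, camera adjusted p = 4.23e-06, and adjusted p = 0.247 with an estimated correlation). The costimulatory receptor Tnfrsf4 was there at 114 ± 33.4 and 214 ± 19.1 CPM (adjusted p = 0.0717). The CD4 count was 4 without Ctrl 3, 3 without Goblet-Y/T 2 and 4 without Goblet-Y/T 3, and Irf1 kept its call in all 6 fits without 1 library. Socs3 lost it without Ctrl 2, Ctrl 3 or Goblet-Y/T 2 (adjusted p of 0.155 to 0.323), Nfkbiz without Ctrl 3, Goblet-Y/T 2 or Goblet-Y/T 3 (0.104 to 0.363) and Socs1 without any library but Ctrl 1 (0.112 to 0.372). Cdkn2d lost it without Ctrl 1, Ctrl 3, Goblet-Y/T 2 or Goblet-Y/T 3 (0.0617 to 0.529), and Ttc28 without Ctrl 3 or any Goblet-Y/T library (0.0563 to 0.364). With sex as a covariate Socs1, Nfkbiz, Cdkn2d and Ttc28 were not called, nor with DESeq2 Socs1, Cdkn2d and Ttc28. The CD8 count was 11 without Ctrl 1, 5 without Goblet-Y/T 1, 2 without Goblet-Y/T 2 and 1 without Ctrl 2, Ctrl 3 or Goblet-Y/T 3, with Sbno2 called in all 6. Gadd45g lost its call without Ctrl 2, Ctrl 3, Goblet-Y/T 2 or Goblet-Y/T 3 and with sex as a covariate. The regulatory count was 31, 7 and 3 without Ctrl 1, 2 and 3 and 6, 0 and 6 without Goblet-Y/T 1, 2 and 3, and Sbno2 lost its call without Goblet-Y/T 2 (adjusted p = 0.185). In NK cells 6 genes passed without Ctrl 1 and 1 without Ctrl 3, and in B cells 1 without Ctrl 2 and 5 without Goblet-Y/T 1. Of the CD4 lists, interferon gamma lost its call without Goblet-Y/T 1 (0.327). NF-kB lost it without Ctrl 2 (0.0755), Ctrl 3 (0.240), Goblet-Y/T 2 (0.0877) or Goblet-Y/T 3 (0.0869). MHC class II lost it without Ctrl 1 (0.321), with the opposite direction without Goblet-Y/T 1 (0.818).

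In non-classical monocyte-like cells F13a1, the A chain of coagulation factor XIII, rose from 16.0 to 50.9 CPM (log2 fold change 1.64 ± 0.15, adjusted p = 2.14e-05 by edgeR's quasi-likelihood test), and the calprotectin subunit gene S100a9 from 22.1 ± 2.61 to 59.6 ± 13.8 CPM (1.38 ± 0.17, 0.00112). The secreted inhibitor Wfdc17 rose from 97.5 to 191.2 CPM (0.97 ± 0.11, 0.000229) and the chemokine receptor Ccr2 to 269.7 CPM (0.85, 0.00117). F13a1 and Ccr2 were also on the marker list of classical monocytes. Cluster 20 of the class, next closest to classical monocytes, held 75, 73 and 42 cells in Ctrl and 55, 79 and 28 in Goblet-Y/T. Cluster 2, the rest of it, held 815, 542 and 263 in Ctrl and 294, 224 and 101 in Goblet-Y/T. Cluster 20 was thus a larger part of the class in each Goblet-Y/T library than in any Ctrl library. Another mix within the class was therefore not told apart from a change of expression. In all, 8 of 8887 genes rose and none fell (DESeq2 called 18), and 23 changed without Ctrl 1. With no cell filter F13a1 (0.31), S100a9, Wfdc17 and Ccr2 were not called (adjusted p = 0.9999 each), nor S100a9 and Ccr2 with doublets kept or S100a9 at Leiden resolution 0.8. Socs3 was among the 8 (0.70), and its call ended without Goblet-Y/T 2 (adjusted p = 0.0508). Neutrophil granule and activation genes had 2 of 10 members up (5 adjusted over the list alone, median 0.81, camera adjusted p = 5.37e-24, and adjusted p = 0.0178 with an estimated correlation). Immediate early genes had 2 of 23 up (6 over the list alone, median 0.22, 6.32e-10, and adjusted p = 0.0221 with an estimated correlation). Type 2 myeloid genes had 1 of 7 up (2 over the list alone, median 0.17, 1.39e-06, and adjusted p = 0.0443 with an estimated correlation). That member was Retnla, at 88.4 UMIs per 1000 of these cells in Goblet-Y/T against 175300 per 1000 interstitial macrophage-like cells, where free RNA is not excluded. Immediate early genes also answer tissue dissociation.

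In classical monocyte-like cells 1 of 8891 genes changed, Ccr1, a receptor for inflammatory chemokines, from 37.3 to 73.0 ± 14.8 CPM (0.98 ± 0.15, adjusted p = 0.0475 by edgeR's quasi-likelihood test). The call ended without Ctrl 2 (0.286), Ctrl 3 (0.0779), Goblet-Y/T 2 (0.291) or Goblet-Y/T 3 (0.389). It ended also with DESeq2 size factors, sex as a covariate, doublets kept, Leiden resolution 0.8 and the automatic doublet threshold (0 genes each). The type I interferon list lay lower there, with 0 of 24 members past the threshold over all genes and 9 down adjusted over the list alone. Its median was -0.38 (camera adjusted p = 4.45e-24, and adjusted p = 0.474 with an estimated correlation), and Ifit1 was at 47.2 ± 13.1 and 21.5 ± 4.13 CPM. In neutrophil-like cells 1 of 6711 genes changed (Retnla, adjusted p = 0.0246, under the 20 CPM required of a named gene, so given after its values were seen; lost with sex as a covariate and without any library but Ctrl 1). It came to 45.3 UMIs per 1000 neutrophil-like cells there, against 175300 per 1000 interstitial macrophage-like cells. The cytokine Tnf was there at 26.8 ± 2.25 and 60.8 ± 12.8 CPM (adjusted p = 0.0502). Proliferating cells, a mix of dividing T, NK, B and macrophage cells, had 1 changed gene of 8892, Tppp3, which promotes tubulin polymerization (65.3 to 245.7 CPM, 1.91 ± 0.16, adjusted p = 0.0193; past the threshold without Ctrl 1 and lost without any other library, with the replicate block, with sex as a covariate and with the stricter cell filter). Without Ctrl 1 the counts were 22 in classical monocyte-like, 40 in neutrophil-like and 1127 in proliferating cells, and without Goblet-Y/T 1 8 in classical monocyte-like cells. The mix of proliferating cells differed between libraries, which was not told apart from a change of expression.

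Summed over all sorted cells, which also moves with the mix of cells, AA467197 rose from 10.5 to 114.7 CPM (log2 fold change 3.44 ± 0.25, adjusted p = 0.0326). Fcrls, an Fc receptor-like gene (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), rose from 13.6 to 31.4 CPM (1.20 ± 0.10, 0.0387). These were 2 of 3 changed genes of 14818 by edgeR's quasi-likelihood test; Fbp1 was the other, and DESeq2 called 267. Type 2 myeloid genes had 0 of 19 members past the threshold and 10 up adjusted over the list alone (median 1.27, camera adjusted p = 5.83e-24). Of the 20 lists that passed, it was the 1 that also did so with an estimated correlation (adjusted p = 0.0465). Its members Retnla, Mgl2 and Ccl17, and also Fcrls, were among the leading genes of the interstitial macrophage-like cluster. That class averaged 1.78% of kept cells in Ctrl and 4.33% in Goblet-Y/T, so a different mix of cells was not told apart from expression here. Cholesterol genes had 15 of 17 up adjusted over the list alone (median 1.11, adjusted p = 1.07e-31, and adjusted p = 0.262 with an estimated correlation). Of the lists from outside the gate, the fibroblast list had a median of -1.30 (summed CPM 240.0 ± 48.4 and 130.6 ± 39.2, exact permutation p = 0.1; camera adjusted p = 1.43e-07, and adjusted p = 0.372 with an estimated correlation), and the erythroid list one of -1.49 (398 ± 292 and 138 ± 82.6 CPM, overlapping, exact p = 0.2, with 734.6 in Ctrl 2 and 237.5 and 221.3 in the other Ctrl libraries; 0.00011, and adjusted p = 0.489 with an estimated correlation). The summed alveolar epithelium (517.4 and 495.6 CPM, exact p = 0.8) and endothelium transcripts (246.1 and 194.2 CPM, exact p = 0.4) differed by less than the spread between libraries. The count was 1238 without Ctrl 1, 0 without Ctrl 2, Ctrl 3 or Goblet-Y/T 2, and 2 without Goblet-Y/T 3; the call of Fcrls ended without any library but Ctrl 1, and that of AA467197 without Ctrl 2 (0.142), Ctrl 3 (0.293) or Goblet-Y/T 2 (0.262). Both ended with sex as a covariate (0.0972).

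Interstitial macrophage-like cells made up 1.78 ± 0.803% of kept cells in Ctrl and 4.33 ± 1.10% in Goblet-Y/T, with all 3 Goblet-Y/T libraries above all 3 Ctrl libraries. CD4 T cell-like cells were at 5.44 ± 0.848% and 3.67 ± 0.273%, and CD8 T cell-like cells at 8.04 ± 1.18% and 5.59 ± 0.696%. Plasmacytoid dendritic cell-like cells, the interferon-producing lineage, were at 0.674 ± 0.123% and 0.315 ± 0.095%. Each of these had all Goblet-Y/T libraries below all Ctrl libraries. For these 4 classes the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Their edgeR quasi-likelihood adjusted p was 0.171 (interstitial, log2 fold change 1.29), 0.325 (CD4, -0.57), 0.337 (CD8, -0.53) and 0.171 (plasmacytoid, -1.09), so that no share passed. Alveolar macrophage-like cells took 7.59 ± 8.91% and 9.35 ± 7.03% (exact p = 0.6) and non-classical monocyte-like cells 10.1 ± 4.39% and 5.27 ± 1.66% (exact p = 0.3). NK cell-like cells took 7.50 ± 1.83% and 4.75 ± 2.77% (exact p = 0.2) and B cell-like cells 32.6 ± 14.1% and 40.6 ± 6.41% (exact p = 0.5). Without Ctrl 1, where B cell-like cells took 16.7%, their difference of 8.04 percentage points came to 0.0645, and that of non-classical monocyte-like cells went from -4.85 to -2.63. Without Goblet-Y/T 1 that of NK cell-like cells went from -2.75 to -1.31. The other 7 classes had exact p between 0.2 and 1. Shares are within the CD45+ Epcam- gate and say nothing of total cell numbers.

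**Figure D2:**
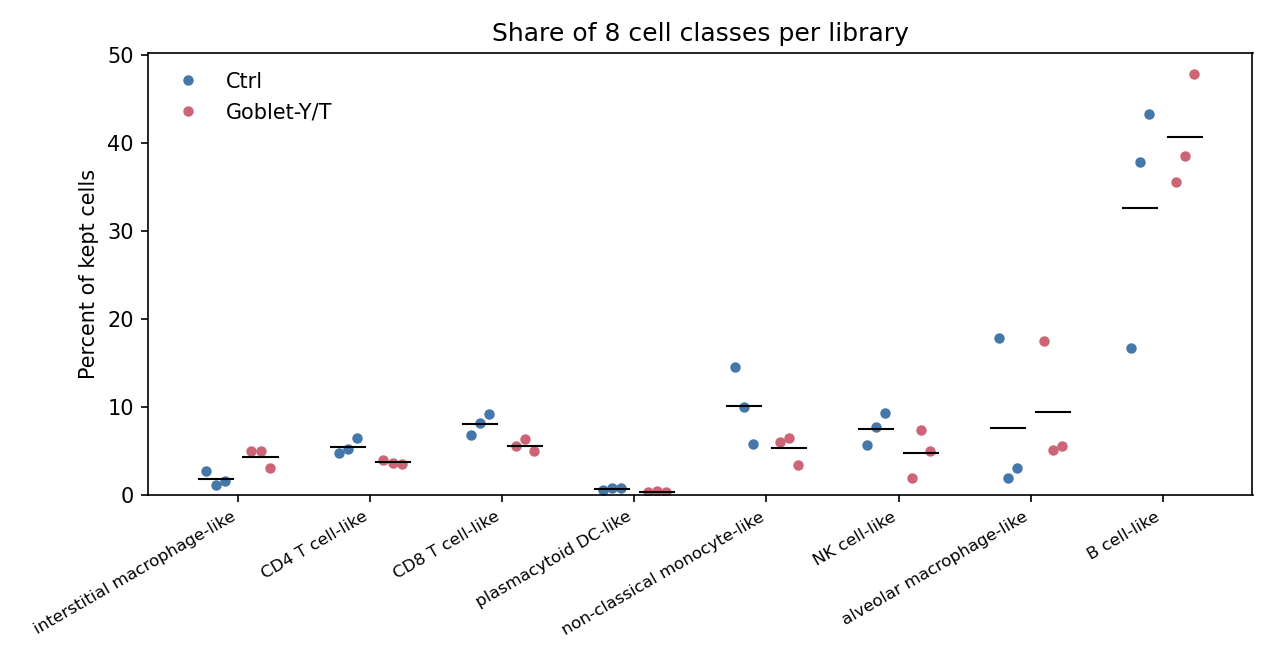
Percent of kept cells in 8 classes for each of the 3 Ctrl and 3 Goblet-Y/T libraries (points), with group means (lines) and no error bars. The interstitial macrophage-like shares average 1.78% in Ctrl and 4.33% in Goblet-Y/T without overlap, and those of alveolar macrophage-like cells overlap.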

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

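The tests of the difference between classes and between sexes, the sex covariate, the comparison of Retnla between classes, the division of the interstitial macrophage-like class into parts and the splits of the libraries were chosen only after the results had been seen. The tests of foreign RNA, of unequal depth and of lymphocytes in the same droplet were not. The test of depth per cell was added after these, before its own value was seen.

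The response to the genotype differed between the alveolar and the interstitial macrophage-like classes for 223 of 10793 genes in a joint fit by edgeR's quasi-likelihood test (1404 at an unadjusted p of 0.05). The log2 fold change was higher in the alveolar class for 168 and lower for 55. The sterol enzymes Fdft1 and Sqle had fold changes 1.71 and 1.57 higher on the log2 scale in the alveolar class (Benjamini-Hochberg adjusted p = 0.0053 and 0.0262). The scavenger receptor Cd36 (-1.69) and the ribonuclease Ear2 (-2.21) had lower ones. The cholesterol list (median difference 1.19, camera adjusted p = 4.35e-20), the type I interferon response (1.18, 2.81e-13) and MHC class II (1.85, 4.24e-11) differed too, each with adjusted p = 0.209 with an estimated correlation.

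Between female and male libraries the response of the alveolar macrophage-like class differed for 1 of 10449 genes (580 at an unadjusted p of 0.05). The male Ctrl and the female Goblet-Y/T arm were 1 library each and have no spread of their own, so this count rests on the spread of the other libraries. It was Tsc22d3, a glucocorticoid-induced leucine zipper gene, named here after its values were seen, with a male minus female difference of 2.05 on the log2 scale (adjusted p = 0.0087 by edgeR's quasi-likelihood test). Its CPM was 187.9 and 204.4 in the female Ctrl libraries, 64.3 in the male one, 41.2 in the female Goblet-Y/T library and 52.5 and 59.6 in the male ones.

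In the alveolar macrophage-like class 2237 genes changed, and the genotype was set against sex, foreign RNA and depth. With sex as a covariate 1924 of the 2237 stayed called with no change of sign, which argues against sex as the whole cause. RNA of interstitial macrophages or dendritic cells was implied at no more than 0.358% by the median of 30 of their transcripts, while the median gene that fell would need 34.5%, and 57.4% of the genes that rose (687 of 1197) lay above the interstitial class in all 3 Goblet-Y/T libraries. After every library was thinned to 2122258 UMIs, the lowest sum over all genes, tested or not, 1486 of the genes stayed called, with 0 sign changes, which argues against unequal totals, though depth per cell still differed. Among cells of 19000.5 to 23499.2 UMIs, a range shared by all libraries (19 to 271 cells each), the median gene of the 2237 kept 0.715 of its log2 fold change, with a median absolute deviation of 0.304, 304 stayed called and 43 had the opposite sign, so depth per cell stays open as part of the pattern.

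Retnla, a resistin-like protein made by the interstitial macrophage-like class (132500 ± 29960 UMIs per 1000 cells in Ctrl and 175300 ± 23800 in Goblet-Y/T, SD, n = 3), passed the threshold in neutrophil-like and non-classical monocyte-like cells. In Goblet-Y/T it stood at 33.1 ± 5.09 UMIs per 1000 B, 26.9 ± 29.9 CD4 T, 24.6 ± 17.8 CD8 T and 32.9 ± 15.6 NK cells, against 6.48, 10.9, 12.4 and 7.08 in Ctrl. The highest of these 4 classes exceeded the lowest 1.35-fold in Goblet-Y/T. Neutrophils (45.3 ± 15.3 UMIs per 1000 cells against 4.73 in Ctrl) exceeded the mean of the 4 1.54-fold. Both lay within the 3-fold band set for free RNA of macrophages, so free RNA could give the level of neutrophils in Goblet-Y/T. The band compares levels within Goblet-Y/T and does not test the rise. In Ctrl neutrophils stood below all 4 classes (4.73 against 6.48 to 12.4). Non-classical monocytes (88.4 ± 27.8 against 20.2) exceeded the Goblet-Y/T mean of the 4 classes 3.01-fold, beyond the band by less than their spread. For them free RNA and expression of their own both stay open. Expression by the lymphocytes or neutrophils themselves was not tested apart from this.

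Cytotoxic genes lay lower in the interstitial macrophage-like class of Goblet-Y/T, and lymphocytes in the same droplet, another mix of cells and a change of expression were weighed. Without cells that held at least 2 UMIs of lymphocyte genes the median log2 fold change of the list was -1.06 and 35 genes changed. That lies beyond the -1 set in advance against this explanation by less than the spread of the members (0.883), a margin added after the value was seen. The list had a median of 0.22 in the interstitial macrophage part and -2.49 in the dendritic part, where 77 genes changed. The parts went opposite ways, which does not decide on another mix of cells. Droplets with lymphocyte RNA, another mix of cells and a change within the dendritic cells therefore all stay open.

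The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05 in any class. In the alveolar macrophage-like class the real split alone (1 of 10) called as many genes (2237; highest other 6), and in the interstitial class likewise (1 of 10; 66; highest other 7). As many genes as the real split were called by 2 splits in all sorted cells (3; highest other 6), CD4 T (9; 12), non-classical monocyte (8; 12) and proliferating cells (1; 3). They were called by 3 in CD8 T cells (2; 21), by 4 in neutrophils (1; 9) and regulatory T cells (1; 7), and by 5 in classical monocytes (1; 8). In B and NK cells, where the real split called 0 genes (275 and 284 at an unadjusted p of 0.05, and 6 and 0 by DESeq2), all 10 did, with up to 58 and 11. The split of the female Ctrl 1, Ctrl 2 and Goblet-Y/T 1 from the male libraries must call the sex-linked genes it was read from. Without genes of chromosomes X and Y it called 51 in B cells, where the real split called 0 and the highest other 1. This points to a structure of these samples along that split in B cells. In CD8 T cells it called 14 and the real split 2, but that of Ctrl 1, Goblet-Y/T 1 and Goblet-Y/T 2 from the rest called 12. In the other classes and all sorted cells the split by sex called 0 to 6. It called 0, 6, 6 and 0 in all sorted, CD4 T, non-classical monocyte and proliferating cells. There no other split then reached the real count (3, 9, 8 and 1).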

How the results depend on the processing

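Among results on single genes, 613 values under other settings kept direction and side of the threshold, 94 kept direction alone and 1 turned, Ms4a4b of the interstitial macrophage-like class, at 0.61 with Leiden resolution 2.5, where the class loses its dendritic part. With 1 library left out 244 kept their call and 146 kept direction alone. In the 8 classes whose shares are reported singly, all 72 values of class abundance under other settings that kept all libraries kept direction and side of the threshold. All 48 values of shares under such settings kept direction. Their side could not change, because the smallest exact p of 3 against 3 is 0.1. Their sizes moved. At Leiden resolution 2.5 the share difference was 1.52 percentage points for interstitial (2.56 in the main setting) and 0.253 for alveolar macrophage-like cells (1.76). With sex as a covariate the log2 fold change of cell numbers was -1.20 for NK (-0.66) and 0.81 for alveolar macrophage-like cells (0.30). Among the other 7 classes the log2 fold change of cell numbers turned in 4, with no call: neutrophils (-0.05; 0.21 with TMM factors and 0.005 with the block) and proliferating cells (-0.20; 0.02 with TMM factors and 0.26 with sex). The others were gamma-delta T cells (0.08; -0.35 with no cell filter and -0.03 with the automatic doublet threshold) and plasma cells (0.85; -0.07 with the block), and the cause was not tested. Classes of few cells had less depth, down to 337478 UMIs in a regulatory T cell sum, and what the gene test recovers at that depth was not simulated. Sex as a covariate, Scrublet's automatic threshold and the wider and narrower alveolar macrophage-like classes were alternatives chosen after seeing the data; the wider class had 2293 changed genes, 2076 of them among the 2237, and the narrower 2229, of which 2201.

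For the count of changed genes, the interstitial macrophage-like class (66) had 198 with DESeq2, 690 with no filter on low counts, 37 with sex as a covariate (30 of the 66 among them) and 4 at Leiden resolution 2.5. CD4 T cells (9) had 18 with no filter on low counts and 5 with sex. Non-classical monocytes (8) had 18 with DESeq2, 53 with no filter on low counts and 3 with no cell filter. All sorted cells (3) had 267 with DESeq2, 9 with no filter on low counts, 1 with sex and 6 with the stricter cell filter. The other 7 classes together (6) had 107 with DESeq2, 186 with no filter on low counts, 18 with sex (14 of them in B cells), 12 with the stricter cell filter, 11 with no cell filter, 14 with doublets kept and 10 with the automatic doublet threshold. With no filter many more genes of few counts enter the test; otherwise the cause was not tested.

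Leaving out 1 library gave 1277 to 2656 changed genes in the alveolar macrophage-like class, 2 to 390 in the interstitial class, 3 to 13 in CD4 T cells, and 6 to 23 in non-classical monocytes. It gave 0 to 1238 in all sorted cells and 2 to 1237 in the other 7 classes together, and the cause was not tested. The log2 fold change of alveolar macrophage-like cell numbers ran from -0.52 to 1.93 and the difference of their share from -2.29 to 6.89 percentage points, turning without Ctrl 2, Ctrl 3 or Goblet-Y/T 1, with no call in any fit. The difference of the B cell share (8.04) ran from 0.0645 without Ctrl 1 to 13.4 without Ctrl 3, with 4.43 without Goblet-Y/T 3. That of NK cells (-2.75) was -1.31 without Goblet-Y/T 1, and that of non-classical monocytes (-4.85) was -2.63 without Ctrl 1. Lists past the threshold numbered 0 with an estimated correlation in the alveolar, interstitial and CD4 classes and 3 in non-classical monocytes. With fry they numbered 1 in the interstitial class, 0 in CD4 T cells and 3 in non-classical monocytes, and with sex as a covariate 6 in CD4 T cells. Of the 12 lists called in the alveolar macrophage-like class 9 also passed with fry. Size factors of DESeq2 ended no list's call. Without 1 library the adjusted p of MHC class II ran from 5.78e-05 to 0.818 in CD4 T cells and from 3.54e-06 to 0.901 in classical monocytes. That of MHC class I in non-classical monocytes ran from 2.48e-06 to 0.960. The direction turned at the highest value of each (without Goblet-Y/T 1, Goblet-Y/T 1 and Ctrl 2).

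With the replicate number as a block, 2489 genes changed in the alveolar macrophage-like class, 119 in the interstitial class, 13 in CD4 T cells, 11 in non-classical monocytes, 76 in all sorted cells and 45 in the other 7 classes together, among them 7 in NK and 0 in proliferating cells. Of 53 list calls 2 ended, MHC class II in CD4 T cells (0.118) and chemokines in non-classical monocytes (0.193). Same-numbered libraries correlated at 0.354, 0.0695 and 0.279 in their deviations from the group means over genes in all sorted cells. Not every pair was over 0.1, and Ctrl 2 correlated more with Goblet-Y/T 3 (0.087). The same-numbered pairs at 0.354 and 0.279 were each of the same sex, and the pair at 0.0695 was not. The same-numbered pairs alone therefore cannot tell pairing by number from sex. Of pairs of the same sex but another number, Ctrl 3 and Goblet-Y/T 2 correlated at 0.271 and Ctrl 2 and Goblet-Y/T 1 at -0.113. In B cell-like cells these stood at 0.389 and 0.293, and the same-numbered pairs at 0.267, -0.373 and 0.382. Among same-numbered pairs only Ctrl 2 and Goblet-Y/T 2 differed in sex, so pairing is not excluded. No pairing was assumed in the main fits.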

Other observations

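The list of origin markers and the list of further liver X receptor targets, and the tests made with them, were chosen only after the results had been seen.

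Dividing cells, a class that mixed T, NK, B and macrophage cells, differed in 16 of 31 lists by camera, 12 higher and 4 lower in Goblet-Y/T. Of the 16, 0 passed with an estimated correlation or with fry. The class held 97, 120 and 33 cells in Ctrl and 121, 38 and 28 in Goblet-Y/T. Cluster 23, next closest to CD8 T cells, held 31, 89 and 26 of them in Ctrl and 14, 16 and 8 in Goblet-Y/T. Cluster 28, next closest to alveolar macrophages, held 63, 9 and 6 and 46, 18 and 13. Cluster 31, next closest to plasma cells, held 3, 22 and 1 and 61, 4 and 7. A shift of this mix was not told apart from changes of expression. The cholesterol list had a median log2 fold change of 1.39, with 16 of 17 members up adjusted over the list alone and 0 over all genes (camera adjusted p = 2.13e-21, and adjusted p = 0.341 with an estimated correlation). Fdps, which makes farnesyl diphosphate, was at 87.7 ± 20.7 and 297.4 ± 135.4 CPM (SD, n = 3) and the squalene epoxidase Sqle at 19.9 and 85.9 CPM. Cytotoxic genes lay lower, with 12 of 14 down adjusted over the list alone and 0 over all genes (median -1.90, adjusted p = 1.25e-16, and adjusted p = 0.341 with an estimated correlation). Granzyme A (Gzma) was at 3486 ± 2163 and 744.6 ± 464 CPM and the chemokine Ccl5 at 3760.0 and 627.9 CPM. The lipid-associated list (5 of 16 up over the list alone, median 1.02, camera adjusted p = 1.32e-10, and adjusted p = 0.341 with an estimated correlation) was higher, with osteopontin (Spp1) at 131.8 ± 128.8 and 1236 ± 739.6 CPM. The cell cycle list was lower (0 of 22 past the threshold, median -0.27, camera adjusted p = 0.00053, and adjusted p = 0.341 with an estimated correlation).

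In B cell-like cells 15 of 29 lists passed camera, none with an estimated correlation. The unfolded protein response lay higher (0 of 12 past the threshold, median 0.27, adjusted p = 7.83e-06, and adjusted p = 0.256 with an estimated correlation), with the chaperone Hspa5 at 231.8 ± 24.3 and 280.8 ± 8.91 CPM. The type I interferon response lay lower (0 of 22, median -0.30, 6.75e-08, and adjusted p = 0.408 with an estimated correlation), and its call ended without Ctrl 3 (adjusted p = 0.400). Cluster 16, B cells led by interferon-induced genes, held 223 cells of Ctrl 3, against 55 and 91 of Ctrl 1 and 2 and 79, 63 and 65 of Goblet-Y/T 1, 2 and 3. Macrophage transcripts were among the higher ones, the chitinase-like gene Chil3 at 21 ± 19.3 and 64.2 ± 26.2 CPM. In regulatory T cell-like cells 7 of 25 lists lay higher by camera, 0 of them with an estimated correlation or with fry, among them T cell activation (2 of 10 up over the list alone, median 0.27, adjusted p = 1.31e-05, and adjusted p = 0.247 with an estimated correlation). The costimulatory receptor Tnfrsf9 was at 5.83 ± 3.08 and 24.9 ± 9.22 CPM. Immediate early genes, which also answer tissue dissociation, lay higher in NK (3 of 20 up over the list alone, median 0.17, adjusted p = 8.66e-05) and CD8 T cells (2 of 20, 0.13, 0.000385), with adjusted p = 0.4705 and 0.4709 with an estimated correlation; the CD8 call ended without Ctrl 3 (0.0580). In CD8 T cells the signalling inhibitor Socs1 (75.2 ± 3.20 and 114.9 ± 11.8 CPM) and Irf1 (108.5 and 157.2) were past the threshold over the interferon gamma list alone (camera adjusted p = 0.0475), with adjusted p = 0.471 with an estimated correlation. That call ended without Ctrl 1 (0.325), Goblet-Y/T 1 (0.320) or Goblet-Y/T 3 (0.0542) and with sex as a covariate (0.0715). NF-kB cytokine genes lay higher in neutrophils (1 of 20 over the list alone, median 0.26, adjusted p = 7.75e-06, and adjusted p = 0.580 with an estimated correlation).

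In all sorted cells the list of Hippo pathway effectors and targets had a median of -0.42 (0 of 9 past the threshold, camera adjusted p = 0.0418, and adjusted p = 0.372 with an estimated correlation). Its call ended without Ctrl 1 (0.154), Ctrl 2 (0.0746), Goblet-Y/T 2 (0.0519) or Goblet-Y/T 3 (0.0627), with the replicate block (0.0809) and with sex as a covariate (0.0818). Its secreted targets Ccn1 (4.37 ± 3.32 and 1.67 ± 0.708 CPM) and Ccn2 (1.41 and 0.444 CPM) stood at levels where fibroblast transcripts also lay lower. The airway secretory list summed to 2.73 ± 1.03 and 2.08 ± 0.601 CPM (exact permutation p = 0.5, n = 3) and the platelet list to 20.2 and 21.5 CPM (exact p = 0.9). Of the clusters left without a name, cluster 34, with alveolar macrophage genes and a high doublet score, held 0.0118 ± 0.0103% of Ctrl and 0.450 ± 0.335% of Goblet-Y/T cells. Cluster 18, with effector CD8 genes, held 4.58% of Ctrl 2 and at most 0.551% of any other library.

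Abca1, Abcg1, Apoe and Mylip, which fell in the alveolar macrophage-like class while sterol synthesis rose, are known targets of the nuclear receptor LXR, so lower activity of LXR is a candidate explanation. Among 9 other known targets 3 fell, Arl4c (-1.48), Plin2 (-0.52) and the lipase Lpl (-1.03), and 2 rose, Lpcat3 (0.41) and Scd2 (1.76). The phospholipid transfer protein Pltp missed the threshold (-1.21, adjusted p = 0.0567 by edgeR's quasi-likelihood test). By the same test Smpdl3a (-0.23, adjusted p = 0.327), Nr1h3 (-0.07, 0.821) and Srebf1 (-0.02, 0.928) did not pass either. The 3 of 9 that fell lie between the bounds set for and against the hypothesis, which stays open.

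A second hypothesis is the arrival of monocyte-derived cells. Of 10 markers of long-term alveolar macrophages 4 fell (Fabp4, Cidec, Pparg and Krt19) and Car4 rose, and of 7 markers of recent monocyte origin 2 rose, Cd14 (224.5 to 407.6 CPM) and the protease Mmp14 (0.181 to 8.68 CPM), and 0 fell. Ly6c2 stood at 5.98 ± 8.30 and 1.96 ± 1.13 CPM and Ccr2 at 10.3 and 13.9. The 4 of 10 that fell lie between the bounds set for and against it, which could leave either a change in resident cells or a replacement of them.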
